A study of Mus musculus with 9 samples.

How the data were processed

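The samples were 9 libraries of mouse bone marrow-derived neutrophils, 3 each from gels of low, middle and high stiffness, as the titles and series description state. Per the labels' protocols, cells stayed in gelatin methacryloyl hydrogel for 2 days in RPMI medium with 10% fetal bovine serum, and the gel was then lysed to release them. RNA was extracted with Trizol and a column kit, and stranded poly(A) libraries were made from 1 μg total RNA and sequenced as 2 reads of 150 bases on an Illumina or MGI instrument. Which instrument served which library, the preparation dates, the purity of the neutrophils, and the sex and age of the mice are not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 (version not given) on GRCm39, and their parameters and the annotation release are not given in the sources used here.

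Each deposited file holds raw counts for 22173 genes in 1 library, with no normalization. It also holds the authors' FPKM, and a column of another unit, the deposited exonic gene size in bases. The deposited FPKM equalled values recomputed from the counts and sizes in 100% of genes, within 0.0051 FPKM, and was not used further. Of the genes, 4937 had 0 counts in every library, and none came from the mitochondrial genome. No coordinates are given, because the reference available here is of another genome build than the files.

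Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings (12094 genes, which held at least 99.9% of each library's counts), normalised by TMM and fitted in 1 quasi-likelihood model with robust dispersion over all 9 libraries. The tests were two-sided contrasts of middle against low, high against low and high against middle, and an F test among the 3 groups, with Benjamini-Hochberg adjusted p under 0.05 within each. The standard error is the size of the log2 fold change divided by the square root of its F statistic. Plots used Python 3.11.15 with matplotlib 3.10.9. These tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to come later.

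The labels number the replicates 1 to 3 but do not say that libraries of the same number belong together. After removal of group means, the 9 pairs of libraries with the same number had correlations of 0.595 to 0.856, which met the condition fixed beforehand for also fitting the number as a block. Most of that structure is replicate 1 against the others. Pairs of replicates 2 and 3 from different groups had correlations of 0.552 to 0.698, and pairs of replicate 1 with 2 or 3 had -0.777 to -0.650. By mean correlation 5 of the 9 libraries were closest to their own number: the replicate 1 libraries, middle replicate 3 and high replicate 3. These correlations therefore do not show that libraries numbered 2, or those numbered 3, belong together across groups. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 5.25 to 12.0 between replicates 2 and 3 and of 147 to 216 for pairs with replicate 1. The biological coefficient of variation was 0.337 without the block and 0.115 with it. Fits with replicates 2 and 3 alone and with a block of 2 levels were chosen after the data were seen.

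For gene lists, 47 were fixed with 794 different symbols, of which 768 are in the files, and the 45 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists within a comparison. Camera was repeated with an estimated correlation, and with all 9 libraries 0 of the 45 lists then passed in any comparison, against 19, 22 and 13 for middle against low, high against low and high against middle with the preset value, and 23, 26 and 18 with the block. NF-kB targets passed with an estimated correlation in replicates 2 and 3 alone for high against low (adjusted p = 0.0325) and middle against low (0.0465). Fry, which asks whether the members of a list move 1 way on balance, called 8 lists for high against low with the block and 0 in the other 5 cases. The 8 included N1 markers (fry adjusted p = 0.0426) but neither NF-kB targets (0.0567) nor interferon-stimulated genes (0.0638). The median, mean and test of a list differed in sign for 8, 6 and 7 lists without the block. The mitochondrial genome list had 0 members in the files, and the sex-linked list had 4 tested members, too few for the test. Its tested member that fell in high was Uty (-0.51 ± 0.14).

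Named genes are, for each comparison, the 10 largest rises and falls among called genes with a mean of at least 5 CPM, no predicted-gene symbol and no overlap between the groups. They also include up to 4 called members of each list with the smallest adjusted p (or its 2 most abundant members where none was called), and every measured polarization marker with Jak1, Stat3 and Piezo1. These last are given in full for high against low and in part for the other comparisons. Some genes and a gene list that met the rules are not reported here. Applying the rule to the fit with the block, with the same direction in all 3 replicates in place of no overlap, was chosen after the data were seen. Groups did not overlap for 7.76%, 12.7% and 5.08% of genes in middle against low, high against low and high against middle, where chance gives 10% if replicate numbers are set aside. Within replicate numbers, 37.3%, 48.5% and 33.6% of genes had the same sign in all 3 pairs, where chance gives 25%.

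The steps were tested on simulated data with the size of the real libraries and 200 changed genes, in 5 draws (raised from 1 after the first draw was seen). With replicate effects as large as the real ones, the fit without the block recovered 21.0% of 2-fold and 65.2% of 4-fold changes with 0 false calls. The fit with the block recovered 96.6% and 99.6%, but 8.23% of its calls were false, above the 5% the threshold allows. Without replicate effects the shares recovered were 11.4% and 75.2% without the block and 4.80% and 65.6% with it. Neither simulation had changes that differ between replicates, so these shares and the false calls do not cover such changes. In the data, high against low fold changes fitted without replicate 1 had a Spearman correlation of 0.318 across genes with the differences in replicate 1. A list shifted by 0.50 was found by camera, with 0 other lists called. The simulated genes were drawn independently, so this does not test for false list calls among genes that move together. In the data the estimated correlation of the interferon-stimulated list was 0.889 for high against low with the block.

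Alternatives were DESeq2 size factors in place of TMM, no filter, a filter at 50 counts, DESeq2 1.42.0 and limma-voom in place of edgeR, fits of only the groups compared, the replicate block, and each library left out in turn. The principal components used log2 CPM with a prior count of 2. No library was left out of the reported results.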

Results

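Gene expression was measured by RNA sequencing in neutrophils taken from mouse bone marrow (wild-type primary cells) and held for 2 days in gelatin methacryloyl hydrogel, a crosslinked gelatin whose stiffness can be set. The series title asks how stiffness acts on neutrophil polarization, the division into a pro-inflammatory state (N1) and an anti-inflammatory state (N2). The gels had a low (1.5 kPa, the control), middle (2.6 kPa) or high (5.7 kPa) stiffness, with 3 libraries in each group and 9 in all. The deposited total counts per library were 13.2 M, 18.3 M and 16.3 M for low replicates 1 to 3. They were 13.2 M, 19.5 M and 14.7 M for middle, and 14.1 M, 18.2 M and 16.0 M for high. Between 14042 and 14914 genes had at least 1 count in a library, and 12094 genes were tested. Genes are named by the symbol the files use as identifier.

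The libraries differed most by replicate number. The first principal component held 68.1% of the variance and set replicate 1 of every group apart from replicates 2 and 3, while the second, with 13.2%, ordered the libraries by stiffness. Between replicate 1 and the mean of replicates 2 and 3, 7909 of the 12094 genes differed (3981 higher and 3928 lower in replicate 1), and between replicates 3 and 2 none did by edgeR (150 at an unadjusted p under 0.05). Each result is therefore given without a term for the replicate number, as fixed before the data were examined, and with the replicate number as a block. Where a count of genes at an unadjusted p under 0.05 is given, chance alone would give a share of about 0.05 of the 12094 tested genes. CPM are TMM-normalised counts scaled to a common library total. Values after gene names are log2 fold changes ± standard error from the fit with the block (n = 3 per group) unless another fit is named. "Rose" and "fell" mean an adjusted p under 0.05 in that fit, from which the counts and medians of gene lists also come. The labels do not say whether replicates are separate animals or cultures or what a replicate number shares, so the p-values measure only the spread between these libraries, which may be technical. Gpnmb, of the macrophage list, had a mean of 3123 CPM, beside 3342 for S100a8, of the mature neutrophil list. Gpnmb was above S100a8 in replicate 1 of every group and below it in every other library. The purity of the neutrophils is not given in the sources used here, so the changes are not assigned to neutrophils alone.

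**Figure D1:**
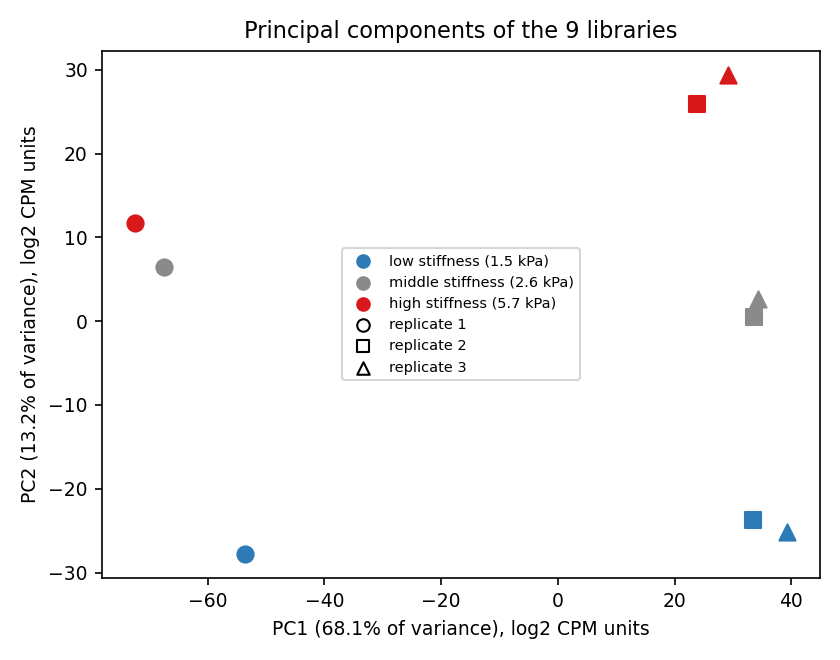
Principal components of the 9 libraries from log2 CPM of the 12094 tested genes, the first component (68.1% of the variance) on the horizontal axis and the second (13.2%) on the vertical axis, with 1 point per library. Replicate 1 of each group lies apart from replicates 2 and 3 on the first axis.

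The comparison of high with low stiffness asks what the largest stiffness step did to the cells. High-stiffness libraries held more Csf3 and Cxcl1 mRNA: Csf3, the granulocyte growth factor, rose by 3.32 ± 0.50 (mean ± SD 11.1 ± 12.7 CPM in low and 83.2 ± 22.5 in high), and Cxcl1, a neutrophil attractant, by 2.21 ± 0.12 (35.2 ± 27.6 against 156 ± 104). Arg1, the arginase used as an N2 marker, rose by 3.24 ± 0.66 and Il12a, an interleukin-12 subunit counted as an N1 marker, by 2.27 ± 0.22. Interferon-inducible genes were lower, among them Iigp1 (-2.45 ± 0.37), Tgtp2 (-2.07 ± 0.24) and Ifit2 (-1.93 ± 0.39). Without the replicate term 11 genes differed in edgeR, 6 higher and 5 lower in high (934 at an unadjusted p under 0.05), and with the block 1869 did, 813 higher and 1056 lower, 420 of them by at least 2-fold. All 11 are among the 1869. From high minus low within replicates 1, 2 and 3, the log2 differences were 2.07, 3.79 and 4.64 for Csf3, 2.04, 2.10 and 2.51 for Cxcl1, 3.43, 1.51 and 4.20 for Arg1 and 1.45, 2.39 and 2.76 for Il12a.

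Of these 11, 10 meet the rule for named genes, with values here from the fit without the replicate term. Higher in high were Sdc1 (2.82 ± 0.34), Phlda1 (1.92 ± 0.22), Cd302 (1.50 ± 0.14), Tes (1.49 ± 0.17) and Treml4 (1.14 ± 0.12), and lower were Gpr162 (-2.10 ± 0.25), N4bp3 (-1.56 ± 0.20), Itgb3 (-1.28 ± 0.15), Pdcd1lg2 (-1.05 ± 0.13) and Hpse (-1.05 ± 0.13). Sdc1 encodes a cell surface heparan sulfate proteoglycan, Tes a focal adhesion protein, Itgb3 an integrin beta chain, Pdcd1lg2 a ligand of the checkpoint receptor PD-1 and Hpse heparanase. The adjusted p was 0.0365 for Tes and 0.0415 for Sdc1. Ptpru (2.56 ± 0.27), named after its values were seen, is the remaining gene, with 0.63 ± 0.125 CPM in low and 3.73 ± 0.267 in high (mean ± SD, n = 3).

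With the block, further rises among the 10 largest were Tmc3 (2.87 ± 0.25), Gja1 (2.68 ± 0.22), Fosl1 (2.11 ± 0.30), Dusp16 (2.08 ± 0.48) and Cass4 (2.02 ± 0.43). Gja1 encodes a gap junction protein, Fosl1 an AP-1 transcription factor and Dusp16 a MAP kinase phosphatase. Sdc1 rose by 2.88 ± 0.34. The further falls among the 10 largest were Cd4 (-2.97 ± 0.39), Axl (-2.11 ± 0.20), Gpr162 (-2.10 ± 0.22), Dnah6 (-2.05 ± 0.19), Spon1 (-1.91 ± 0.27), Rab15 (-1.89 ± 0.21) and Kdr (-1.80 ± 0.22). Axl encodes a receptor kinase used in clearing dying cells, and Kdr a VEGF receptor.

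**Figure D2:**
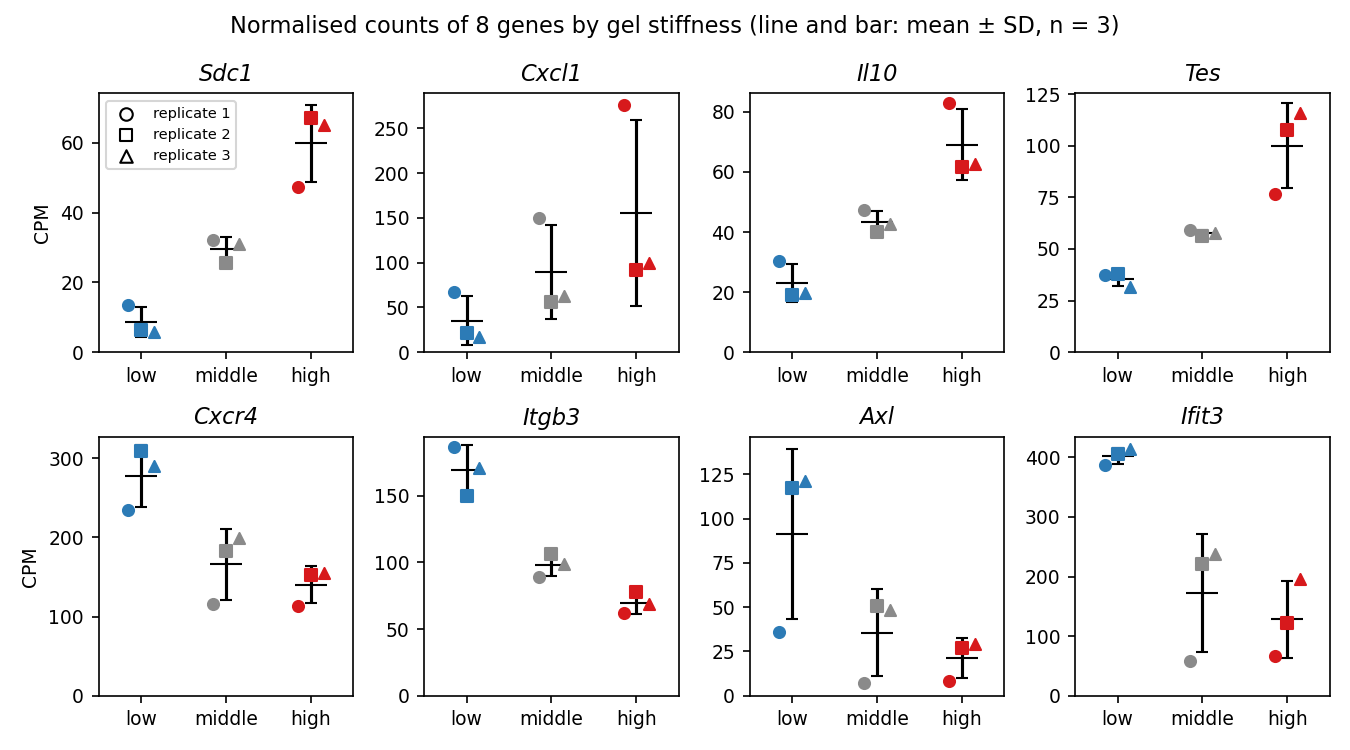
CPM (vertical axis, linear) of 8 genes, chosen after their values were seen, in the low, middle and high groups (horizontal axis), with 1 point per library and the mean ± SD (n = 3) as line and bar. Sdc1, Cxcl1, Il10 and Tes were higher in high than in low in every replicate, and Cxcr4, Itgb3, Axl and Ifit3 lower.

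Polarization markers were the subject of the series. Of 14 tested N1 markers, 7 rose and 0 fell (10 and 1 when adjusted over the list alone). Their median was 0.55 (camera adjusted p = 1.72e-05 without the block and 2.27e-07 with it, adjusted p = 0.227 and 0.333 with an estimated correlation). The members that rose were Il12a (2.27 ± 0.22), Il1b (0.98 ± 0.21), Il12b (0.78 ± 0.23), Ccl4 (0.67 ± 0.09), Ccl3 (0.57 ± 0.12), Tnf (0.52 ± 0.08) and Fas (0.50 ± 0.09). The members that did not pass were Cd80 (1.27 ± 0.32), Il6 (0.96 ± 0.65), Icam1 (0.28 ± 0.12), Nos2 (0.24 ± 0.09), Cxcl10 (0.17 ± 0.30), Cd86 (0.08 ± 0.25) and Il18 (-0.42 ± 0.18), and Cxcl9 was too low to test. The mean difference of the list was 0.17, 0.77 and 0.96 in replicates 1, 2 and 3. Of 13 tested N2 markers, 3 rose and 3 fell (3 and 3 when adjusted over the list alone). Their median was -0.02 (camera adjusted p = 0.912 without the block and 0.665 with it). Arg1, Il10 (1.60 ± 0.10) and Il4ra (0.52 ± 0.11) rose, and Cxcr4 (-0.99 ± 0.10), Prok2 (-0.91 ± 0.20) and Ccl2 (-0.61 ± 0.15) fell. The members that did not pass were Mrc1 (-0.02 ± 0.37), Tgfb1 (0.05 ± 0.11), Vegfa (-0.24 ± 0.10), Mmp9 (0.13 ± 0.11), Ccl5 (-0.09 ± 0.44), Chil3 (-0.74 ± 0.34) and Cd274 (-0.01 ± 0.10), and Ccl17 and Retnla were not tested. In replicates 2 and 3 alone Mrc1 (-0.52) was lower in high and passed the test. Among 3 genes named beforehand for signalling and mechanosensing, Jak1 (0.01 ± 0.09) and Stat3 (0.10 ± 0.12) did not pass and the channel gene Piezo1 (-0.37 ± 0.11) fell.

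NF-kB targets were higher in high, while other inflammatory lists held rises and falls. Of 24 NF-kB targets and regulators, 12 rose and 0 fell (20 and 0 when adjusted over the list alone). Their median was 0.65 (camera adjusted p = 1.13e-18 without the block and 2.65e-13 with it, adjusted p = 0.227 and 0.333 with an estimated correlation). Examples were Sod2 (1.22 ± 0.12), Nfkb1 (0.80 ± 0.09) and Nfkbib (0.45 ± 0.08). The mean difference of this list was 0.13, 0.92 and 0.95 in replicates 1, 2 and 3. With replicates 2 and 3 alone the NF-kB list also passed with an estimated correlation (adjusted p = 0.0325). Of 17 chemokines, 6 rose and 3 fell (6 and 6 when adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.189 without the block and 0.0076 with it, adjusted p = 0.48 and 0.354 with an estimated correlation). The chemokine median and test differ in sign. Cxcl3 (1.80 ± 0.14) and Cxcl2 (1.14 ± 0.14) rose with Cxcl1 and Ccl4. Of 15 inflammasome and pyroptosis genes, 2 rose and 1 fell (5 and 2 when adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.0464 without the block and 0.12 with it, adjusted p = 0.57 and 0.62 with an estimated correlation). Nlrp3 (1.16 ± 0.28), an inflammasome sensor gene, rose and Aim2 (-0.50 ± 0.09) fell. Of 19 pattern recognition receptors, 4 rose and 5 fell (8 and 7 when adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.237 without the block and 0.787 with it). The lipopolysaccharide co-receptor gene Cd14 (1.34 ± 0.22) rose, and Tlr7 (-0.80 ± 0.10), Cd180 (-1.10 ± 0.15) and Clec7a (-0.46 ± 0.10) fell. Of 25 JAK-STAT genes, 4 rose and 2 fell (7 and 3 when adjusted over the list alone). Their median was 0.01 (camera adjusted p = 0.421 without the block and 0.371 with it). Socs3 (1.07 ± 0.15), Pim1 (0.62 ± 0.15), Cish (0.93 ± 0.21) and Csf2rb (0.51 ± 0.11) rose. Of 19 immediate early genes, 1 rose and 3 fell (3 and 5 when adjusted over the list alone). Their median was -0.20 (camera adjusted p = 0.346 without the block and 0.623 with it). Ier3 (0.61 ± 0.10) rose and Fos (-0.79 ± 0.20), Jun (-0.83 ± 0.18) and Dusp1 (-0.62 ± 0.18) fell. Of 21 apoptosis and survival genes, 3 rose and 2 fell (4 and 2 when adjusted over the list alone). Their median was 0.01 (camera adjusted p = 0.44 without the block and 0.676 with it). Birc3 (0.70 ± 0.15) and Bcl2a1b (0.88 ± 0.21) rose and Bid (-0.31 ± 0.08) fell.

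Interferon-stimulated genes were lower in high. Of 28 interferon-stimulated genes, 0 rose and 8 fell (0 and 27 when adjusted over the list alone). Their median was -1.08 (camera adjusted p = 6.01e-20 without the block and 1.08e-18 with it, adjusted p = 0.303 and 0.333 with an estimated correlation). Examples of falls were Irgm1 (-0.91 ± 0.19), Ifi47 (-0.87 ± 0.16) and Bst2 (-0.84 ± 0.10), and Ifit3 was at -1.84 ± 0.44 (adjusted p = 0.0561). The mean difference of the list was -1.90, -0.97 and -0.61 in replicates 1, 2 and 3. Of 13 MHC class I genes, 0 rose and 7 fell (0 and 9 when adjusted over the list alone). Their median was -0.57 (camera adjusted p = 5.00e-08 without the block and 7.14e-06 with it, adjusted p = 0.303 and 0.362 with an estimated correlation). H2-Q4 (-0.90 ± 0.18), H2-T23 (-0.85 ± 0.12), H2-K1 (-0.70 ± 0.15) and B2m (-0.61 ± 0.11) fell, B2m being the shared light chain of class I molecules. Of 10 MHC class II genes, 1 rose and 1 fell (1 and 1 when adjusted over the list alone). Their median was 0.05 (camera adjusted p = 0.783 without the block and 0.547 with it). Cd74 (0.36 ± 0.10) rose and Ctss (-0.44 ± 0.10) fell.

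Genes of glucose use and redox balance were mostly higher in high. Of 20 glycolysis enzymes and transporters, 10 rose and 2 fell (11 and 2 when adjusted over the list alone). Their median was 0.36 (camera adjusted p = 3.75e-04 without the block and 3.27e-05 with it, adjusted p = 0.303 and 0.333 with an estimated correlation). Slc2a1 (0.85 ± 0.08), Slc16a3 (0.81 ± 0.10) and Aldoc (1.13 ± 0.16) rose, encoding a glucose transporter, a lactate transporter and an aldolase, and Hk3 (-0.45 ± 0.10) fell. Of 24 hypoxia targets, 11 rose and 0 fell (11 and 0 when adjusted over the list alone). Their median was 0.35 (camera adjusted p = 2.65e-04 without the block and 1.64e-05 with it, adjusted p = 0.303 and 0.333 with an estimated correlation). Hilpda (0.92 ± 0.11), Ero1a (0.54 ± 0.10) and Egln1 (0.48 ± 0.09) rose with Slc2a1. Of 15 NRF2 targets, 8 rose and 0 fell (11 and 0 when adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.00178 without the block and 2.46e-05 with it, adjusted p = 0.48 and 0.333 with an estimated correlation). Srxn1 (0.66 ± 0.09), Txnrd1 (0.56 ± 0.09), Gsr (0.55 ± 0.10) and Gclm (0.51 ± 0.10) rose. Of 20 cholesterol synthesis genes, 5 rose and 0 fell (5 and 1 when adjusted over the list alone). Their median was 0.33 (camera adjusted p = 2.62e-04 without the block and 8.31e-04 with it, adjusted p = 0.436 and 0.362 with an estimated correlation). Insig1 (0.71 ± 0.12) and Cyp51 (0.56 ± 0.11) rose. Of 19 unfolded protein response genes, 5 rose and 1 fell (9 and 2 when adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.0387 without the block and 0.0141 with it, adjusted p = 0.436 and 0.333 with an estimated correlation). Asns (0.70 ± 0.12), Slc7a11 (0.44 ± 0.12) and Hspa5 (0.31 ± 0.08) rose and Ddit3 (-0.31 ± 0.08) fell.

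Genes of degradation and of the basic cell machinery were more mixed. Of 27 lysosome genes, 1 rose and 13 fell (1 and 18 when adjusted over the list alone). Their median was -0.37 (camera adjusted p = 3.89e-04 without the block and 6.97e-05 with it, adjusted p = 0.48 and 0.37 with an estimated correlation). Npc2 (-0.43 ± 0.10) fell and Ctsl (0.62 ± 0.11) rose. Of 16 lipid efflux and foam-cell genes, 1 rose and 4 fell (1 and 5 when adjusted over the list alone). Their median was -0.60 (camera adjusted p = 0.0464 without the block and 0.0503 with it, adjusted p = 0.303 and 0.483 with an estimated correlation). Nr1h3 (-1.05 ± 0.23), Gpnmb (-1.04 ± 0.20) and Myo5a (-0.55 ± 0.09) fell and Abca1 (0.56 ± 0.10) rose. Of 22 nuclear genes of the respiratory chain, 0 rose and 0 fell (0 and 0 when adjusted over the list alone). Their median was 0.16 (camera adjusted p = 0.0344 without the block and 0.0115 with it, adjusted p = 0.697 and 0.681 with an estimated correlation). The most abundant of them were Atp5b (0.20 ± 0.09) and Atp5a1 (0.16 ± 0.10). Of 33 cytosolic ribosomal protein genes, 1 rose and 0 fell (0 and 0 when adjusted over the list alone). Their median was 0.14 (camera adjusted p = 0.0722 without the block and 0.0145 with it, adjusted p = 0.856 and 0.711 with an estimated correlation). Rpl10 (0.33 ± 0.10) rose. Of 12 heat shock genes, 0 rose and 0 fell (0 and 0 when adjusted over the list alone). Their median was -0.03 (camera adjusted p = 0.994 without the block and 0.97 with it). The most abundant were Hsp90ab1 (0.17 ± 0.09) and Hspa8 (0.01 ± 0.08). Of 15 p53 targets, 1 rose and 3 fell (2 and 3 when adjusted over the list alone). Their median was -0.22 (camera adjusted p = 0.207 without the block and 0.135 with it). Sesn1 (-0.61 ± 0.13), Trp53inp1 (-0.53 ± 0.08) and Bbc3 (-0.41 ± 0.12) fell and Cdkn1a (0.43 ± 0.13) rose.

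Neutrophil genes moved in both directions. The granule lists are given as fixed beforehand, though their members Igsf6 and Arg2 are not established as genes of granule proteins. Of 23 mature neutrophil markers, 9 rose and 4 fell (9 and 4 when adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.0344 without the block and 0.0273 with it, adjusted p = 0.647 and 0.383 with an estimated correlation). Fpr1 (1.22 ± 0.11), Fpr2 (1.07 ± 0.13) and Slpi (1.02 ± 0.13) rose, the first pair encoding formyl peptide receptors. Of 16 secondary and tertiary granule genes, 4 rose and 4 fell (4 and 5 when adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.423 without the block and 0.428 with it). In replicates 2 and 3 alone that list was lower in high and passed the test with the preset correlation (median -0.14), but not with an estimated correlation (adjusted p = 0.354). Lcn2 (1.32 ± 0.16), Chil1 (1.17 ± 0.13), Hp (1.01 ± 0.14) and Arg2 (0.60 ± 0.10) rose. Of 9 primary granule genes, 1 rose and 4 fell (1 and 6 when adjusted over the list alone). Their median was -1.16 (camera adjusted p = 0.119 without the block and 0.0076 with it, adjusted p = 0.71 and 0.333 with an estimated correlation). Elane (-1.77 ± 0.30), Prtn3 (-1.08 ± 0.29) and Prss57 (-2.47 ± 0.58) fell, the first pair encoding elastase and proteinase 3, and Igsf6 (0.37 ± 0.10) rose. Of 8 NADPH oxidase genes, 3 rose and 0 fell (4 and 0 when adjusted over the list alone). Their median was 0.24 (camera adjusted p = 0.0772 without the block and 0.0076 with it, adjusted p = 0.436 and 0.333 with an estimated correlation). Rac2 (0.55 ± 0.09) and Cybb (0.44 ± 0.09) rose. Of 9 extracellular trap genes, 1 rose and 3 fell (1 and 4 when adjusted over the list alone). Their median was -0.02 (camera adjusted p = 0.723 without the block and 0.163 with it). Padi4 (-0.46 ± 0.10) and Serpinb1a (-0.69 ± 0.15) fell with Elane.

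Genes of adhesion and matrix were also tested. Of 26 integrin and focal adhesion genes, 8 rose and 4 fell (8 and 4 when adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.912 without the block and 0.626 with it). Itga2 (-1.95 ± 0.26), Itga6 (-1.21 ± 0.15) and Itgb3 (-1.29 ± 0.11) fell and Itga1 (1.52 ± 0.20) rose. Of 15 YAP and TAZ targets and mechanosensitive channel genes, 2 rose and 4 fell (2 and 4 when adjusted over the list alone). Their median was -0.12 (camera adjusted p = 0.841 without the block and 0.631 with it). Myof (-0.48 ± 0.11) fell with Axl, and Wwtr1 (1.20 ± 0.23) and F3 (1.01 ± 0.26) rose. Of 24 matrix genes, 7 rose and 5 fell (8 and 5 when adjusted over the list alone). Their median was 0.20 (camera adjusted p = 0.131 without the block and 0.101 with it). Fn1 (1.99 ± 0.27) and Thbs1 (0.68 ± 0.14) rose and Plau (-1.09 ± 0.11) and Timp3 (-0.93 ± 0.21) fell. Of 13 angiogenic factors, 3 rose and 3 fell (3 and 3 when adjusted over the list alone). Their median was -0.24 (camera adjusted p = 0.769 without the block and 0.943 with it). Areg (2.80 ± 0.59) rose and Hgf (-0.69 ± 0.16) and Vegfb (-0.62 ± 0.16) fell.

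Markers of proliferating cells, of progenitors and of other cell types were mostly lower in high. The progenitor list shares Mpo and Elane with the primary granule list, so it does not stand for cells outside the neutrophil line alone. Genes with a mean under 1 CPM had a median high minus low change of -0.22, and those above 256 of 0.06, so genes of low abundance had slightly lower values in high as a class. Of 32 cell cycle genes, 0 rose and 15 fell (0 and 17 when adjusted over the list alone). Their median was -0.51 (camera adjusted p = 0.00108 without the block and 2.27e-07 with it, adjusted p = 0.647 and 0.354 with an estimated correlation). Cenpf (-1.50 ± 0.28), Cenpe (-1.26 ± 0.21), Rrm2 (-1.02 ± 0.18) and Top2a (-0.86 ± 0.09) fell. Of 13 progenitor markers, 0 rose and 5 fell (0 and 9 when adjusted over the list alone). Their median was -0.94 (camera adjusted p = 0.0017 without the block and 2.46e-05 with it, adjusted p = 0.57 and 0.333 with an estimated correlation). Myb (-1.42 ± 0.19), Gfi1 (-0.94 ± 0.26) and Cebpe (-0.71 ± 0.20) fell. Of 12 megakaryocyte and platelet markers, 0 rose and 7 fell (0 and 9 when adjusted over the list alone). Their median was -1.07 (camera adjusted p = 0.0078 without the block and 8.85e-06 with it, adjusted p = 0.578 and 0.333 with an estimated correlation). Tubb1 (-1.38 ± 0.12), Gp5 (-1.22 ± 0.26), Itga2b (-0.96 ± 0.14) and Vwf (-0.54 ± 0.11) fell. Of 13 mast cell, basophil and eosinophil markers, 0 rose and 5 fell (0 and 7 when adjusted over the list alone). Their median was -1.21 (camera adjusted p = 2.46e-04 without the block and 3.89e-05 with it, adjusted p = 0.48 and 0.333 with an estimated correlation). Prg3 (-2.18 ± 0.56), Epx (-1.47 ± 0.29), Ear6 (-1.26 ± 0.32) and Ccr3 (-0.91 ± 0.21) fell.

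Markers of lymphoid and myeloid cells followed the same pattern in part. Of 13 dendritic cell markers, 0 rose and 4 fell (0 and 7 when adjusted over the list alone). Their median was -0.72 (camera adjusted p = 2.28e-04 without the block and 0.00117 with it, adjusted p = 0.227 and 0.333 with an estimated correlation). Siglech (-1.42 ± 0.41), Ccl22 (-0.94 ± 0.27) and Irf8 (-0.70 ± 0.14) fell. Of 9 T and NK cell markers, 0 rose and 2 fell (0 and 3 when adjusted over the list alone). Their median was -0.95 (camera adjusted p = 0.0344 without the block and 0.00578 with it, adjusted p = 0.436 and 0.333 with an estimated correlation). Il7r (-0.61 ± 0.12) fell with Cd4. Of 12 B and plasma cell markers, 1 rose and 4 fell (1 and 6 when adjusted over the list alone). Their median was -0.70 (camera adjusted p = 0.466 without the block and 0.0147 with it, adjusted p = 0.908 and 0.533 with an estimated correlation). Rag1 (-1.20 ± 0.25), Pax5 (-0.96 ± 0.20) and Ebf1 (-0.92 ± 0.24) fell, and the member that rose is Sdc1. Of 23 macrophage markers, 5 rose and 8 fell (5 and 13 when adjusted over the list alone). Their median was -0.75 (camera adjusted p = 0.0137 without the block and 0.00901 with it, adjusted p = 0.303 and 0.362 with an estimated correlation). Vcam1 (-1.16 ± 0.20) and Mertk (-0.94 ± 0.12) fell with Gpnmb, and Cd163 (2.02 ± 0.29) rose. Of 14 monocyte markers, 5 rose and 3 fell (6 and 3 when adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.0393 without the block and 0.00451 with it, adjusted p = 0.63 and 0.333 with an estimated correlation). F13a1 (0.69 ± 0.13) and Csf1r (0.59 ± 0.10) rose with Fn1 and Treml4. Of 6 osteoclast markers, 0 rose and 2 fell (0 and 2 when adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.388 without the block and 0.152 with it). Tnfrsf11a (-0.60 ± 0.13) and Ctsk (-0.57 ± 0.11) fell. Of 11 erythroid markers, 0 rose and 0 fell (0 and 0 when adjusted over the list alone). Their median was -0.48 (camera adjusted p = 0.199 without the block and 0.253 with it). The most abundant were Hbb-bs (-0.44 ± 0.40) and Hba-a1 (-0.16 ± 0.41). Of 13 stromal and endothelial markers, 0 rose and 3 fell (2 and 5 when adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.0554 without the block and 0.0857 with it). Col1a2 (-1.04 ± 0.26) and Col1a1 (-0.67 ± 0.17) fell with Kdr.

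Several lists had another result in replicates 2 and 3 alone. Passing the camera test there, but not in either fit of all libraries, were erythroid markers (median -0.99, camera adjusted p = 1.42e-05, or 0.248 with an estimated correlation), of which 10 of 11 were called lower, JAK-STAT genes (median 0.16, camera adjusted p = 0.00418, or 0.354 with an estimated correlation), extracellular trap genes (median -0.05, camera adjusted p = 0.0198, or 0.248 with an estimated correlation) and stromal and endothelial markers (median -0.50, camera adjusted p = 0.00996, or 0.248 with an estimated correlation). Lipid efflux and foam-cell genes passed there (median -0.89, camera adjusted p = 1.18e-08, or 0.22 with an estimated correlation), with mean differences of 0.14, -0.76 and -0.68 in replicates 1, 2 and 3. The sign in replicate 1 was also opposite, among others, for macrophage markers (0.11, -0.58 and -0.46), inflammasome genes (-0.03, 0.35 and 0.48) and erythroid markers (0.71, -0.65 and -1.03). Mature neutrophil markers (adjusted p = 0.07), respiratory chain genes (adjusted p = 0.284), chemokines (adjusted p = 0.075), ribosomal protein genes (adjusted p = 0.116) and B and plasma cell markers (adjusted p = 0.213) did not pass in replicates 2 and 3.

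**Figure D3:**
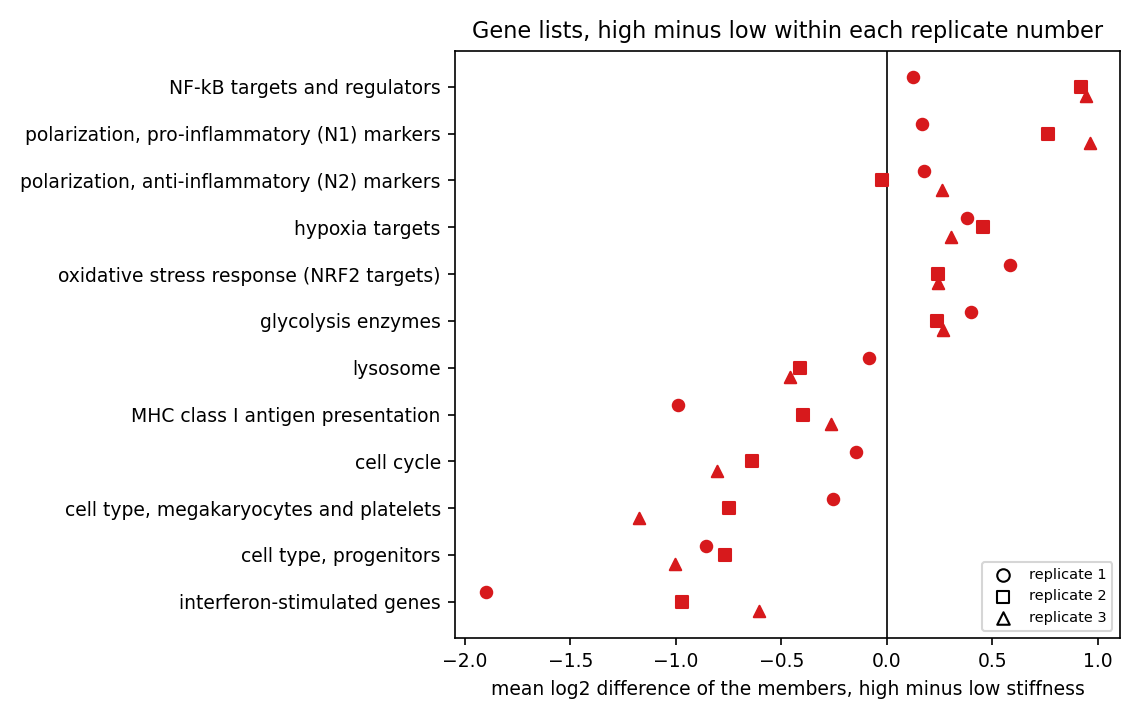
Mean log2 difference of the members of 12 lists, high minus low (horizontal axis), within each replicate number (1 point per replicate, lists on the vertical axis). Interferon-stimulated genes were lower in every replicate (-1.90, -0.97 and -0.61), and NF-kB targets were higher by 0.13 in replicate 1 and by 0.92 and 0.95 in replicates 2 and 3.

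In the high against low comparison the call of 11 genes was not stable: there were 0 without low replicate 2, low replicate 3, middle replicate 2, middle replicate 3, high replicate 2 or high replicate 3, 2 without middle replicate 1, 5 without low replicate 1 and 41 without high replicate 1, 0 when only the 6 libraries of these groups were fitted, and 333 with DESeq2. With the block the count was 605 without high replicate 2, 808 without low replicate 3, 914 without high replicate 3 and 1049 without low replicate 2. In replicates 2 and 3 alone 3207 genes differed, and 73.2% of those with a replicate 1 value had the same sign in replicate 1. Across genes the fold changes in replicates 2 and 3 had a Spearman correlation of 0.318 with the differences in replicate 1. The fit with the block assumes the same change in every replicate. The values above show that changes in replicate 1 often differed in sign or size from those in replicates 2 and 3. The NF-kB list, for example, had a mean difference of 0.13 in replicate 1 and of 0.92 and 0.95 in replicates 2 and 3. A called change is therefore an average that need not hold in each replicate, and replicate 1 has only 1 library per group.

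The comparison of middle with low stiffness asks whether a small step already moves the same genes. Cxcl1 rose by 1.45 ± 0.12, the acute phase gene Saa3 (1.52 ± 0.18) rose, and Il12a rose by 1.46 ± 0.22, while Axl (-1.51 ± 0.19), Cd4 (-1.93 ± 0.35) and H2-Q7 (-1.36 ± 0.28) fell. Further rises were Tmc3 (1.69 ± 0.26), Gja1 (1.52 ± 0.23), Plxdc2 (1.41 ± 0.21), Fosl1 (1.39 ± 0.30), Aldoc (1.33 ± 0.16), Wfdc21 (1.25 ± 0.21) and Phlda1 (1.22 ± 0.13), and further falls Tgtp2 (-1.33 ± 0.23), Dnah6 (-1.30 ± 0.18), Kdr (-1.22 ± 0.21), Rab15 (-1.20 ± 0.20), Gpr162 (-1.18 ± 0.20), Stra6l (-1.17 ± 0.17) and Rnf144b (-1.11 ± 0.20). Without the replicate term edgeR called 0 genes (smallest adjusted p 0.366, 318 genes at an unadjusted p under 0.05), and with the block 222 (98 higher and 124 lower in middle).

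Of 14 N1 markers, 1 rose and 0 fell (7 and 0 when adjusted over the list alone). Their median was 0.28 (camera adjusted p = 0.00729 without the block and 1.07e-04 with it, adjusted p = 0.308 and 0.376 with an estimated correlation). Their mean difference was -0.01, 0.43 and 0.48 in replicates 1, 2 and 3. Il12a was the member that rose, and the others lay between Cd86 (-0.45 ± 0.26) and Il12b (0.85 ± 0.23). Of 13 N2 markers, 1 rose and 1 fell (3 and 1 when adjusted over the list alone). Their median was -0.13 (camera adjusted p = 0.811 without the block and 0.654 with it). Il10 (0.94 ± 0.10) rose and Cxcr4 (-0.77 ± 0.10) fell, and Arg1 (2.41 ± 0.68) did not pass. Jak1 (-0.04 ± 0.09), Stat3 (-0.07 ± 0.12) and Piezo1 (-0.25 ± 0.11) did not pass.

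Of 24 NF-kB targets and regulators, 2 rose and 0 fell (4 and 0 when adjusted over the list alone). Their median was 0.28 (camera adjusted p = 1.53e-10 without the block and 4.02e-08 with it, adjusted p = 0.301 and 0.401 with an estimated correlation). Sod2 (0.75 ± 0.12) and Nfkb1 (0.47 ± 0.09) rose. The list passed with an estimated correlation as well in replicates 2 and 3 alone (adjusted p = 0.0465), while its mean difference was 0.04, 0.47 and 0.50 in replicates 1, 2 and 3. Of 28 interferon-stimulated genes, 0 rose and 1 fell (0 and 4 when adjusted over the list alone). Their median was -0.78 (camera adjusted p = 3.13e-24 without the block and 4.01e-24 with it, adjusted p = 0.301 and 0.376 with an estimated correlation). Bst2 (-0.71 ± 0.10) fell. The mean difference of the list was -1.70, -0.45 and -0.42 in replicates 1, 2 and 3, and its median in replicates 2 and 3 alone was -0.38. Of 13 MHC class I genes, 0 rose and 1 fell (0 and 7 when adjusted over the list alone). Their median was -0.46 (camera adjusted p = 8.65e-11 without the block and 4.02e-08 with it, adjusted p = 0.237 and 0.376 with an estimated correlation). H2-T23 (-0.67 ± 0.12) fell. Of 27 lysosome genes, 0 rose and 1 fell (1 and 9 when adjusted over the list alone). Their median was -0.27 (camera adjusted p = 7.35e-05 without the block and 4.26e-06 with it, adjusted p = 0.443 and 0.376 with an estimated correlation). Ctsk (-0.56 ± 0.11) fell. Of 23 macrophage markers, 0 rose and 1 fell (3 and 8 when adjusted over the list alone). Their median was -0.59 (camera adjusted p = 8.32e-04 without the block and 3.27e-05 with it, adjusted p = 0.158 and 0.376 with an estimated correlation). Mertk (-0.70 ± 0.12) fell. Of 26 integrin and focal adhesion genes, 1 rose and 3 fell (2 and 4 when adjusted over the list alone). Their median was 0.03 (camera adjusted p = 0.265 without the block and 0.447 with it). Vasp (0.50 ± 0.11) rose and Itga6 (-0.90 ± 0.14) and Itgb3 (-0.79 ± 0.11) fell. Of 23 mature neutrophil markers, 3 rose and 1 fell (4 and 2 when adjusted over the list alone). Their median was 0.05 (camera adjusted p = 0.0766 without the block and 0.0548 with it). Fpr1 (0.79 ± 0.11) and Fpr2 (0.66 ± 0.12) rose. Further lists called without the replicate term included, with the median log2 fold change in that fit and the camera p-values, dendritic cells (-0.37, adjusted p = 9.86e-05, or 0.158 with an estimated correlation), cell cycle (-0.30, adjusted p = 0.0229, or 0.851 with an estimated correlation), megakaryocytes and platelets (-0.74, adjusted p = 0.0165, or 0.84 with an estimated correlation) and progenitors (-0.36, adjusted p = 0.0232, or 0.846 with an estimated correlation). To these came mast cells, basophils and eosinophils (-0.37, adjusted p = 0.0154, or 0.84 with an estimated correlation), hypoxia targets (0.23, adjusted p = 0.00367, or 0.425 with an estimated correlation), glycolysis enzymes (0.20, adjusted p = 0.00137, or 0.311 with an estimated correlation) and cholesterol biosynthesis (0.25, adjusted p = 2.35e-05, or 0.345 with an estimated correlation). The same holds for mitochondrial respiratory chain (0.12, adjusted p = 0.0481, or 0.851 with an estimated correlation), lipid efflux and foam-cell genes (-0.33, adjusted p = 9.29e-04, or 0.158 with an estimated correlation), stromal and endothelial cells (-0.55, adjusted p = 4.46e-04, or 0.301 with an estimated correlation) and erythroid cells (-0.41, adjusted p = 0.0165, or 0.483 with an estimated correlation). Of these lists, mast cell, basophil and eosinophil markers (adjusted p = 0.912) and respiratory chain genes (adjusted p = 0.506) did not pass in replicates 2 and 3 alone. NADPH oxidase genes (adjusted p = 0.112) and NRF2 targets (adjusted p = 0.23), called with the block, did not pass there either. Passing there, but in neither fit of all libraries, were immediate early genes (median 0.15, adjusted p = 4.64e-07), inflammasome genes (median 0.05, adjusted p = 0.00334), JAK-STAT genes (median 0.10, adjusted p = 0.00358) and MHC class II genes (median 0.21, adjusted p = 0.00717), with adjusted p of at least 0.278 with an estimated correlation. Erythroid markers had mean differences of 0.28, -0.77 and -0.69 in replicates 1, 2 and 3.

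DESeq2 called 48 genes without the replicate term. With the block the count was 27 without low replicate 3, 35 without middle replicate 1, 50 without middle replicate 3, 55 without middle replicate 2, 80 without low replicate 2, 134 without high replicate 2, 476 without high replicate 1 and 661 without low replicate 1. In replicates 2 and 3 alone 784 genes differed, 78.0% of those with a replicate 1 value having the same sign there.

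The comparison of high with middle stiffness asks whether the second step adds to the first. Of the genes that rose most in high against low, Cxcl1 (0.75 ± 0.11), Arg1 (0.83 ± 0.55), Csf3 (1.39 ± 0.45) and Sdc1 (1.04 ± 0.30) had higher values in high than in middle, none passing the test. Without the replicate term edgeR called 0 genes (179 at an unadjusted p under 0.05, 2 called by DESeq2), and with the block 2, both higher in high. These are Car3 and Cyp2e1, carbonic anhydrase and cytochrome P450 genes named after their values were seen. Counts for low replicates 1 to 3, then middle, then high were 11, 93, 131, 0, 1, 8, 13, 111 and 82 for Car3 (adjusted p = 0.0287). For Cyp2e1 they were 63, 26, 23, 0, 0, 0, 74, 12 and 16 (adjusted p = 0.0488), so it was at 0 in every middle library. Both belong with liver and fat transcripts that appeared in only part of the libraries, such as Alb (309 counts in low replicate 1, 356 in high replicate 1 and 0 elsewhere).

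Of 14 N1 markers, 0 rose and 0 fell (3 and 0 when adjusted over the list alone). Their median was 0.31 (camera adjusted p = 9.26e-05 without the block and 4.97e-06 with it, adjusted p = 0.541 and 0.504 with an estimated correlation). Of 13 N2 markers, 0 rose and 0 fell (1 and 0 when adjusted over the list alone). Their median was -0.02 (camera adjusted p = 0.893 without the block and 0.723 with it). Of 24 NF-kB targets and regulators, 0 rose and 0 fell (2 and 0 when adjusted over the list alone). Their median was 0.33 (camera adjusted p = 1.61e-13 without the block and 4.10e-10 with it, adjusted p = 0.541 and 0.504 with an estimated correlation). Of 28 interferon-stimulated genes, 0 rose and 0 fell (0 and 0 when adjusted over the list alone). Their median was -0.28 (camera adjusted p = 8.72e-04 without the block and 1.63e-04 with it, adjusted p = 0.868 and 0.708 with an estimated correlation). Of 24 matrix genes, 0 rose and 0 fell (7 and 1 when adjusted over the list alone). Their median was 0.24 (camera adjusted p = 8.72e-04 without the block and 1.24e-04 with it, adjusted p = 0.597 and 0.504 with an estimated correlation). Of 32 cell cycle genes, 0 rose and 0 fell (0 and 4 when adjusted over the list alone). Their median was -0.32 (camera adjusted p = 0.0144 without the block and 4.97e-06 with it, adjusted p = 0.868 and 0.504 with an estimated correlation). Other lists called without the replicate term, with the median log2 fold change in that fit, were progenitors (-0.50, adjusted p = 0.022, or 0.868 with an estimated correlation), mast cells, basophils and eosinophils (-0.84, adjusted p = 0.00288, or 0.644 with an estimated correlation), T and NK cells (-0.56, adjusted p = 0.0393, or 0.644 with an estimated correlation) and hypoxia targets (0.13, adjusted p = 0.0144, or 0.644 with an estimated correlation). To these came oxidative stress response (NRF2 targets) (0.20, adjusted p = 0.0104, or 0.644 with an estimated correlation), unfolded protein response (0.14, adjusted p = 0.0124, or 0.541 with an estimated correlation), inflammasome and pyroptosis (0.11, adjusted p = 0.019, or 0.644 with an estimated correlation) and pattern recognition receptors (0.13, adjusted p = 0.0393, or 0.541 with an estimated correlation). Mean differences in replicates 1, 2 and 3 were 0.10, -0.35 and -0.54 for cell cycle genes, 0.34, -0.65 and -0.74 for progenitor markers and 0.02, -0.75 and -0.81 for mast cell, basophil and eosinophil markers. Passing in replicates 2 and 3 alone, but in neither fit of all libraries, were macrophage markers (median -0.26, adjusted p = 2.37e-05), immediate early genes (median -0.30, adjusted p = 8.40e-04), lysosome genes (median -0.15, adjusted p = 8.67e-04), extracellular trap genes (median -0.02, adjusted p = 0.00106), secondary and tertiary granule genes (median -0.25, adjusted p = 0.00201), dendritic cell markers (median -0.33, adjusted p = 0.0107), apoptosis and survival genes (median 0.08, adjusted p = 0.0187), NADPH oxidase genes (median 0.18, adjusted p = 0.0409) and erythroid markers (median -0.36, adjusted p = 0.0409), with adjusted p of at least 0.15 with an estimated correlation. Chemokines (adjusted p = 0.273) and ribosomal protein genes (adjusted p = 0.0772), called with the block, did not pass there.

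With the block the count for high against middle was 0 without middle replicate 2, 1 without high replicate 2, 4 without low replicate 2, 8 without middle replicate 1, 11 without high replicate 3, 254 without low replicate 1 and 301 without high replicate 1, and in replicates 2 and 3 alone 840 genes differed (63.3% of those with a replicate 1 value with the same sign there).

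Across all 3 groups at once, edgeR called 0 genes without the replicate term (smallest adjusted p 0.0935, 551 at an unadjusted p under 0.05, 197 with DESeq2) and 1089 with the block. The count was 1 without low replicate 1 and 12 without high replicate 1 without the replicate term. It was 332 without high replicate 2, 375 without low replicate 3, 489 without low replicate 2, 536 without high replicate 3, 646 without middle replicate 3 and 1826 without low replicate 1 with the block, and 2490 in replicates 2 and 3 alone.

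Genes called against low in both stiffer groups moved the same way in both. A test of the middle group against the mean of the others called 0 genes without the replicate term (61 at an unadjusted p under 0.05) and 2 with the block, Car3 and Cyp2e1, both lower in middle, which are the pair named above among liver and fat transcripts found in part of the libraries. By edgeR, 0 of the genes called against low were called in both comparisons without the replicate term (45 with DESeq2), and with the block 215 were called in both in the same direction (96 higher and 119 lower) and 0 in opposite directions. With independent calls 6.59 higher and 10.8 lower would be shared by chance. Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson correlation of 0.752 with the block and a covariance of 0.125. In 20 simulated data sets that reuse the low libraries without a stiffness effect the means were 0.493 and 0.0260. Genes were drawn independently there, so a shift shared by many genes in the low libraries was not simulated. Both comparisons use the same 3 low libraries, which cannot be split further.

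**Figure D4:**
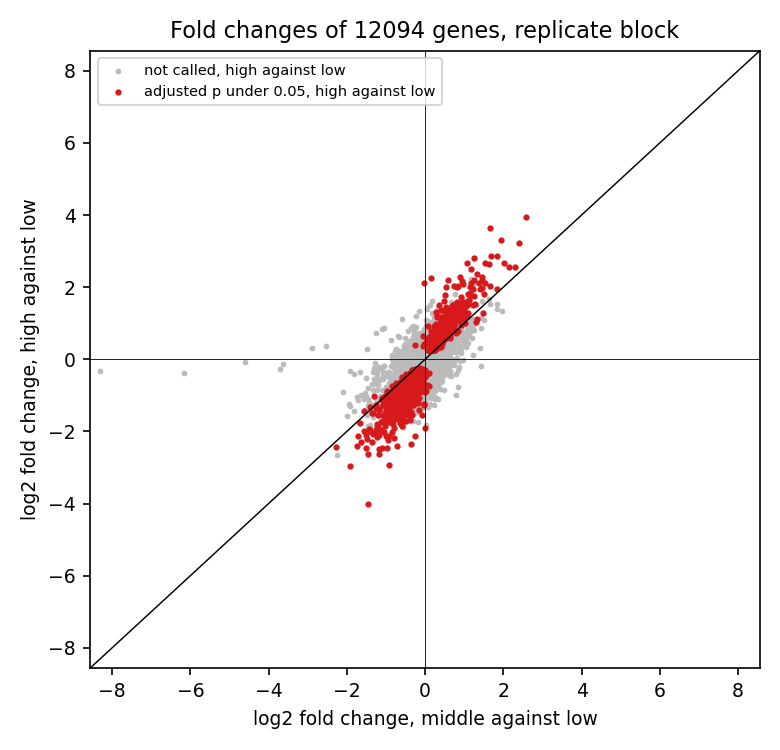
Log2 fold change of high against low (vertical axis) plotted against middle against low (horizontal axis) for the 12094 tested genes, from the fit with the replicate block, with 1 point per gene and the line of equal change. The 1869 genes called in high against low are drawn in red.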

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

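Replicates 2 and 3 alone, the block of 2 levels and all alternatives run with the block were chosen after the data were seen, while the block itself was planned. The gene counts depend most on how replicate 1 is treated, and the list calls on the correlation that camera uses. Counts are in the order middle against low, high against low, high against middle and among the 3 groups, where 0, 11, 0 and 0 genes were called. They were 48, 333, 2 and 197 with DESeq2, 222, 1869, 2 and 1089 with the block, 784, 3207, 840 and 2490 in replicates 2 and 3 only and 354, 2276, 16 and 1442 with the block of 2 levels. High against low gave 0 with only those groups fitted, and 0 to 41 with 1 library left out, and the test among the 3 groups 0 to 12. The overlap of calls against low, 0 genes, was 45, 215, 739 and 340 in the same order of settings. With the block, middle against low (222) gave 340 with no filter, 462 with DESeq2, 825 in replicates 2 and 3 and 27 to 661 with 1 library left out. High against low (1869) gave 3183 and 605 to 2469 in those last settings, and the test among the 3 groups (1089) 2535 and 332 to 1826. High against middle (2) gave 1 with DESeq2 size factors, 40 with no filter, 0 with the filter at 50 counts, 108 with DESeq2, 1 with limma-voom, 900 in replicates 2 and 3 and 0 to 301 with 1 library left out. Of the lists, 19, 22 and 13 were called in the comparisons, 0, 0 and 0 with an estimated correlation, and for high against middle 26 in replicates 2 and 3 and 7 to 21 with 1 library left out. Fewer libraries leave fewer degrees of freedom when 1 is left out; otherwise the cause was not tested.

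Among values for named genes in the fit without the block, 1379 kept their direction and side of the threshold, 622 came to pass it and 14 no longer did, with libraries left out counted apart (1905, 8 and 85). Of the 622, 182 came with the block, 185 with the block of 2 levels and 195 in replicates 2 and 3 only. Many of the genes were named for passing with the block, so this gain was partly fixed in advance. With the filter at 50 counts the test turned for lists with medians of -0.16 (YAP and TAZ targets), 0.0043 (heat shock proteins) and 0.081 (integrins and focal adhesion). With only the groups compared the test turned for lists with medians of -0.13 (YAP and TAZ targets). With only the groups compared the genes on the other side of 0 were Cd274 (0.0012). With the replicate block the test turned for lists with medians of -0.12 (YAP and TAZ targets), -0.030 (heat shock proteins) and 0.090 (integrins and focal adhesion). With the replicate block the genes on the other side of 0 were Ccl5 (-0.087), Hba-a1 (-0.16) and Mrc1 (-0.021). In replicates 2 and 3 only the test turned for lists with medians of 0.087 (YAP and TAZ targets), 0.034 (angiogenic factors), -0.017 (heat shock proteins), -0.099 (immediate early genes), 0.10 (integrins and focal adhesion), -0.095 (N2 markers), -0.018 (N2 markers (high against middle)) and -0.14 (secondary and tertiary granule proteins). In replicates 2 and 3 only the genes on the other side of 0 were Cd274 (0.13), Hba-a1 (-0.77), Mmp9 (-0.010), Mrc1 (-0.52), Stat3 (middle against low) (0.10) and Tgfb1 (-0.14). With the block of 2 levels the test turned for lists with medians of -0.14 (YAP and TAZ targets), -0.030 (heat shock proteins) and 0.089 (integrins and focal adhesion). With the block of 2 levels the genes on the other side of 0 were Ccl5 (-0.073), Hba-a1 (-0.16) and Mrc1 (-0.018). With no filter the test turned for lists with medians of -0.23 (angiogenic factors) and 0.10 (integrins and focal adhesion). With limma-voom the genes on the other side of 0 were Ccl5 (-0.10) and Hba-a1 (-0.21). With 1 library left out, gene values that changed sign covered Atp5b -0.023 to 0.40, Bid -0.86 to 0.24, Ccl5 -0.31 to 0.51, Cd274 -0.070 to 0.098, Cd86 -0.12 to 0.54, Ctsk -2.23 to 1.10, Ctsk (middle against low) -2.16 to 1.04, Cxcl10 -0.099 to 0.57 and Ddit3 -1.40 to 0.79. The ranges for more genes were Gclm -0.082 to 1.08, Hba-a1 -0.88 to 0.53, Hk3 -1.08 to 0.17, Hspa8 -0.050 to 0.12, Il12b -0.22 to 1.83, Il7r -1.67 to 0.46, Jak1 -0.030 to 0.11, Mmp9 -0.44 to 0.46 and Mrc1 -0.36 to 0.35. Last came Nos2 -0.21 to 0.72, Rab15 (middle against low) -2.44 to 0.10, Stat3 -0.0089 to 0.44, Stat3 (middle against low) -0.16 to 0.23, Tgfb1 -0.15 to 0.13 and Vwf -1.51 to 0.45. For lists whose test turned, medians covered JAK-STAT signalling -0.065 to 0.27, MHC class II -0.18 to 0.37, YAP and TAZ targets -0.31 to 0.15, angiogenic factors -0.31 to 0.010, cell cycle (middle against low) -0.62 to 0.044, B and plasma cells -1.31 to -0.28, mast cells, basophils and eosinophils (middle against low) -0.71 to 0.11 and progenitors (middle against low) -0.77 to 0.074. More list ranges were cytosolic ribosomal proteins -0.13 to 0.40, heat shock proteins -0.24 to 0.15, integrins and focal adhesion -0.10 to 0.26, integrins and focal adhesion (middle against low) -0.20 to 0.16, interferon-stimulated genes (high against middle) -0.64 to 0.021, mature neutrophil markers (middle against low) -0.28 to 0.35, mitochondrial respiratory chain (middle against low) -0.066 to 0.24 and neutrophil extracellular trap components -0.17 to 0.023. Remaining list ranges were NRF2 targets (high against middle) -0.083 to 0.60, N2 markers -0.22 to 0.11, N2 markers (high against middle) -0.043 to 0.071, N2 markers (middle against low) -0.15 to 0.12, primary granule proteins -1.60 to -0.69 and secondary and tertiary granule proteins -0.50 to 0.27. These values come from fits without the block unless a block is named. There, leaving out a library gave the groups unequal shares of replicate 1, which differed from the others in 7909 genes. How much of each range comes from this was not tested, nor was any further cause. At totals of 13.2 M to 19.5 M counts the filter left 12094 of 22173 genes to test, and whether more depth would add genes was not tested.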

Other observations

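Replicate 1 of every group differed from replicates 2 and 3 in many neutrophil genes (fit with the block, genes chosen after their values were seen). Of 16 secondary and tertiary granule genes, 0 were higher and 15 lower in replicate 1 (median -1.85, camera adjusted p = 1.97e-12, adjusted p = 0.345 with an estimated correlation). Examples were Ngp (-4.58 ± 0.35), Ltf (-3.71 ± 0.30) and Camp (-1.87 ± 0.47). Of 9 primary granule genes, 0 were higher and 9 lower in replicate 1 (median -2.64, camera adjusted p = 7.45e-05, adjusted p = 0.292 with an estimated correlation). Of 23 mature neutrophil markers, 3 were higher and 18 lower in replicate 1 (median -1.54, camera adjusted p = 3.02e-08, adjusted p = 0.292 with an estimated correlation). S100a8 (-1.82 ± 0.20) and S100a9 (-1.95 ± 0.14) were lower in replicate 1, being among the abundant cytosolic proteins of neutrophils. Of 32 cell cycle genes, 2 were higher and 28 lower in replicate 1 (median -1.48, camera adjusted p = 3.02e-08, adjusted p = 0.504 with an estimated correlation). Mki67 (-1.86 ± 0.09) and Top2a (-2.20 ± 0.08) were lower. Of 33 cytosolic ribosomal protein genes, 30 were higher and 0 lower in replicate 1 (median 0.66, camera adjusted p = 7.71e-08, adjusted p = 0.504 with an estimated correlation). Of 27 lysosome genes, 17 were higher and 4 lower in replicate 1 (median 0.37, camera adjusted p = 0.00216, adjusted p = 0.522 with an estimated correlation). Ctsk (2.90 ± 0.09) was among the higher ones.

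Some transcripts known from liver or fat appeared in only part of the libraries, a set chosen after the values were seen. Alb, the albumin gene, had 309 counts in low replicate 1, 356 in high replicate 1 and 0 in the other 7 libraries. Apoa1 had 50 and 48 counts in the same pair of libraries and at most 1 elsewhere, and Ttr 26 and 33 counts there and 0 elsewhere. Adipoq, a fat cell hormone gene, had 18 and 19 counts in low replicates 2 and 3, 19 and 24 in high replicates 2 and 3, 0 in both replicate 1 libraries of those groups and 3 to 4 in the middle libraries. Cfd had 38 and 27 counts in low replicates 2 and 3, 42 and 34 in high replicates 2 and 3, and 0, 1 and 7 in the middle libraries. Car3 and Cyp2e1, the genes called between high and middle with the block, belong to this set, and whether RNA of other tissues was carried over was not tested.

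Tests of cell composition, other cell types, a ceiling and exchanged libraries, and the splits with the block, were chosen after the results were seen. The setting apart of replicate 1 (7909 genes) stayed after thinning all libraries to the smallest total, with 7788 genes, 7717 of them shared. The fold changes are already scaled to the total, so thinning could hardly remove these calls and does not decide about the total. The deviation of genes from their mean went with gene length at a Spearman correlation of -0.347 to -0.146 in the replicate 1 libraries and of 0.151 to 0.283 in the others, so a difference in RNA quality or library making stays open. The setting apart stayed after a correction for gene length, with 7762 genes, 6712 of them shared, which argues against length as the whole cause. A lower share of neutrophils would raise the markers of all other cell types, but 7 of 11 such lists had an upper quartile under 0 in replicate 1. Among the 7 is the progenitor list (upper quartile -0.88). It shares Mpo and Elane with the primary granule list, so its lower values do not count against a lower share. A larger share of a single type stays open, and no further biological explanation was tested. The labels name 3 kinds of sequencing instrument without saying which library had which, so a sequencing batch also stays open.

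Interferon-stimulated genes were lower in stiffer gels (median -1.08, high minus low). Thinning to equal library totals left the median at -1.09, and 9 members fell. The fold changes are already scaled to the total, so thinning could hardly move the median and does not decide about the total. A loss of cells of another type that carry these transcripts stays open, since the mast cell, basophil and eosinophil list had the lowest lower quartile among the other cell types, -1.37 (median -1.21), and mean differences of -1.52, -0.78 and -0.82 in replicates 1, 2 and 3, beside -1.90, -0.97 and -0.61 for the interferon-stimulated genes. That list is a weak candidate, as it summed to only 104 ± 20.7 CPM in low and 54.1 ± 24.3 in high (mean ± SD, n = 3, Prg2 at 30 ± 18.5 and 12.5 ± 6.58), against 7324 ± 411 and 3531 ± 1709 for the interferon-stimulated genes. The abundant macrophage list (9146 ± 135 CPM in low and 6169 ± 1843 in high) had mean differences of 0.11, -0.58 and -0.46. Its members moved both ways (5 rose and 8 fell), and they include Arg1, which was higher in high in every replicate. The mean therefore does not decide whether macrophages were the source in replicate 1. A response of the neutrophils to stiffness also stays open, and no sort or purity is given in the sources used here.

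NF-kB targets had a larger high minus low difference in replicates 2 and 3 than in replicate 1, with an excess in the list mean of 0.81 that was not tested as a list. After thinning to equal library totals the excess was 0.81. CPM are already scaled to the total, so thinning could hardly move this value and does not decide about the total. A ceiling common to all replicates is argued against, as the high library of replicate 1 lay at -0.34 from the mean of the other high libraries, which differed from each other by 0.01. The low library of replicate 1 started higher, with a list mean of 7.80 against 7.33 and 7.32 in low replicates 2 and 3, which is the larger part of the excess. With the middle and high libraries of replicate 1 exchanged, the excess would be 0.90, larger than with the labels given, which argues against an exchange as its cause. Replicate 1 stands apart in other ways as well, and no further explanation was tested.

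Other splits of the same libraries were counted for each result. Without the block, 10 of the 10 splits for middle against low gave as many genes (real 0, highest other 0), 1 of 10 for high against low (real 11, highest other 0), and 10 of 10 for high against middle (real 0, highest other 0). Exchanging labels within replicate numbers, 1 of the 4 splits gave as many genes for middle against low (real 222, highest other 1), 1 of 4 for high against low (real 1869, highest other 0) and 1 of 4 for high against middle (real 2, highest other 0). These splits are too few for a share under 0.05. Among the 3 groups without the block, 100 of the 100 splits drawn from 280 gave as many genes as the real one (real 0, highest other 6373). Where the real count is 0, any split gives as many, so these counts decide nothing about chance. The 2 drawn splits with the replicate 1 libraries as a group gave 6217 and 6373 genes, the other 97 gave 0, and a split by replicate number gave 5979, a structure of the samples. With the block, 1 of the 36 relabelings gave as many genes (real 1089, highest other 541, with middle and high exchanged in replicate 1). That share is under 0.05 only if replicates 2 and 3 count as independent. No gene differed between them by edgeR, and the labels do not say whether they are separate cultures, so chance is not excluded.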
